A study of Mus musculus with 10 samples.

How the data were processed

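Nuclei were isolated from mouse heart tissue and sequenced as 10x Genomics Chromium 3' (v3.1) libraries, per the labels loaded to a target of 10000 nuclei after filters of 100 and 20 µm. The 10 libraries hold injured tissue 7 days after infarction from IgG-treated (3) and hENPP1mAb-treated (3) mice and uninjured tissue (4). Per the submitters' processing notes, Cell Ranger (version not given in the sources used here), Seurat 4.3.0 and the genome build mm10 were used. The deposited matrices hold raw UMI counts per barcode for 32285 features, whole numbers with no normalization, and the authors had already called the barcodes. The lowest UMI count per barcode was 1059, 822 and 785 in IgG 1 to 3, 723, 545 and 660 in hENPP1mAb 1 to 3, and 500 in each uninjured library. Nothing in the labels says whether each library is a separate animal, so the p-values measure only the spread between libraries.

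Of 99567 barcodes, 4475 with fewer than 300 genes or over 5% mitochondrial counts were left out. Scrublet's automatic threshold marked under 0.5% of barcodes in 6 of 10 libraries and 18.6% in another, so the barcodes with the highest scores were removed instead, at 0.8% per 1000 barcodes (4.22% to 9.59% per library, 7515 in all). Nearest neighbours were also found over all libraries together, without joint clusters. Per class and group, 88.3% to 99.8% of a nucleus's neighbours came from its own group, where 9.21% to 61.9% were expected. From its own library came 30.0% to 78.3%. Each library was clustered on its own in scanpy 1.11.5 (2000 variable genes, 30 principal components, 20 neighbours, Leiden resolution 1, igraph 0.11.9, seed 1). Clusters were named by the mean of the 4 highest marker log folds, which had to reach 1.0, with at least 3 markers over 1.5-fold and seen in 5% of nuclei, and with the second class below 0.7 of the first. This naming rule was revised after the clusters were seen. Of 206 clusters (19 to 24 per library), 157 were named and 49 were not: 27 mixed, 15 led by genes of another class, 5 led by mitochondrial genes, 1 led by skeletal muscle genes and 1 with a low score. Unnamed nuclei made up 5.75% to 18.7% of nuclei in IgG, 2.18% to 9.46% in hENPP1mAb and 6.39% to 9.87% in uninjured libraries.

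UMIs were summed per library and class, and a class was tested when every library of both groups held at least 30 nuclei of it, which left 6 classes. All nuclei together were fitted as well. CPM of single genes within a class are UMIs of a gene in such a sum, scaled to the library's total times its TMM factor. CPM of marker sums, of single genes over all nuclei and in the figure of Enpp1 and markers are scaled to the plain total. Genes were tested two-sided with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) on all 10 libraries with group as the only term, TMM scaling, filterByExpr (at least 10 counts in a library and 15 in total) and Benjamini-Hochberg adjustment within a class at 0.05. Gene lists, 22 of pathways and cell states and 16 of cell type markers fixed before the data were examined, were tested with camera (limma 3.58.1) at its preset correlation of 0.01, adjusted over 154 tests of pathway lists per comparison. Some splits of the libraries that mixed the groups called about as many lists, so a small camera p alone does not tie a list to the groups. The choices of tests, gene lists, named genes and alternatives were made before the data were examined, except where said otherwise. A count "adjusted over the list alone" uses Benjamini-Hochberg adjustment over the measured members only. Estimated correlations come from the residuals of the same fit and were computed for the pathway lists, not for the marker lists, and fry was run as another alternative. Shares of nuclei were compared with two-sided exact permutation tests adjusted over 6 classes. For 3 against 3 libraries the smallest p is 0.1, for 6 against 4 it is 0.00476, and for 3 against 4 it is 0.0286 over 35 splits, where the planned design had taken 0.05 to be out of reach.

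Named genes were chosen by rule: per comparison and class, the 3 with the largest increase and the 3 with the largest decrease among genes called, with an average log CPM of at least 4 and no overlap between the groups' libraries, and up to 4 members of smallest p of each list called. Predicted, mitochondrially encoded and sex-linked genes were left out of the ranking. Enpp1 and Cdkn1a in each class, Nppa, Nppb, Myh7 and Ankrd1 in cardiomyocytes, Postn, Col1a1, Acta2 and Cthrc1 in fibroblasts, and Spp1, Trem2, Ccr2 and Lyve1 in monocytes and macrophages were always taken. The text names part of the list members. A fold against a group with 0 counts is a bound from a floor of 3 counts over the group, and with 1 to 3 counts a ratio is given with an exact 95% interval for the counts. Intervals and floors cover counting error only.

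Free RNA was estimated per library and class as the library's profile over all nuclei, scaled by the level of the markers of other classes within the class. Per gene, the share of the class's counts that it could give was averaged over libraries, and a gene counted as mostly free RNA above 0.5. The estimated share of all counts was 19.4%, 13.8% and 15.6% of cardiomyocyte counts in IgG, hENPP1mAb and uninjured libraries, 41.2%, 47.2% and 22.6% in fibroblasts, and 50.8%, 64.0% and 48.7% in monocytes and macrophages. In hENPP1mAb 1 it was 68.3% in fibroblasts and 20.4% in cardiomyocytes, against 33.5% to 39.7% and 10.02% to 10.99% in the other 2 hENPP1mAb libraries, so the order of IgG and hENPP1mAb in fibroblasts rests on 1 library. Markers of each class were also summed within the other classes. Gene positions came from GENCODE for GRCm38, where 32158 of 32285 features (99.6%) matched by identifier.

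The fits were tested on simulated data with 200 genes changed, and the shares below are of those still tested after the low-count filter. Far more genes were called in the deposited counts, so the adjusted threshold was less strict there. For hENPP1mAb against IgG, 3.13%, 47.0% and 90.6% of changes of 1.5, 2 and 4-fold were recovered in cardiomyocytes (6.19% of calls false), 23.9%, 58.5% and 89.1% in fibroblasts (7.5%), 1.52%, 41.8% and 90.5% in endothelial (12.2%), 7.94%, 47.7% and 84.1% in endocardial (7.29%), 3.28%, 26.6% and 85.5% in mural (11.1%), and 1.54%, 24.6% and 87.5% in monocyte and macrophage nuclei (7.59%). For IgG against uninjured, the shares were 1.54%, 43.9% and 89.2% in cardiomyocytes (5.38%), 15.2%, 61.2% and 84.9% in fibroblasts (7.76%), 1.54%, 30.3% and 83.3% in endothelial (10.1%), 6.15%, 40.3% and 92.1% in endocardial (3.33%), 4.62%, 30.3% and 78.5% in mural (3.9%), and 0%, 22.4% and 85.7% in monocyte and macrophage nuclei (8%).

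The relation between the comparisons was set beside 10 simulations with no antibody effect, in which each gene was drawn on its own. Alternatives covered RLE scaling and DESeq2 1.42.0, no low-count filter, only the 2 groups compared, a replicate block by label number, each library left out, stricter filters on nuclei (500 genes, 1%), doublets kept, Leiden resolution 2, nuclei thinned to at most 1000 UMIs, and other denominators. Nuclei of at least 1100 UMIs, genes with at most 0.5 of their counts from free RNA, and a denominator of named nuclei were chosen after seeing the data. Other scalings moved the median log2 fold change of all genes by -0.02 to 0.02. Libraries were checked for duplicates within groups, and none were found (chi-square per degree of freedom from 4.56 to 147). Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.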

Results

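Single-nucleus RNA sequencing was carried out on heart tissue of mice whose label reads humanized ENPP1, on a C57BL/6NT background. ENPP1 is an ectonucleotidase, an enzyme on the cell surface that cleaves extracellular nucleotides such as ATP. The 10 libraries fall into 3 groups. The IgG group (control antibody, n = 3) and the hENPP1mAb group (monoclonal antibody against human ENPP1, n = 3) hold injured heart tissue taken 7 days after myocardial infarction, and the uninjured group (n = 4) holds heart tissue without infarction. Deposited counts totalled 30314356, 19788435 and 26047082 unique molecular identifiers (UMIs) in IgG 1, 2 and 3. They totalled 36547148, 31647884 and 30160356 in hENPP1mAb 1, 2 and 3, and 15271471, 20525213, 13644731 and 15258614 in uninjured 1 to 4. The median UMI count per barcode ran from 2001 to 2514.5 in IgG, from 1633 to 2004 in hENPP1mAb and from 920 to 1022 in uninjured libraries. After filtering, 87577 nuclei were left, from 5059 to 10837 per library. Clusters were named from fixed marker genes, and 6 cell classes had enough nuclei in every library to be tested.

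The first question was which cell classes made up the tissue in each group. Cardiomyocytes made up 34.8% ± 2.55 (SD, n = 4) of nuclei in uninjured libraries, 9.14% ± 4.76 (n = 3) in IgG and 23.2% ± 6.46 (n = 3) in hENPP1mAb. Monocytes and macrophages made up 7.15% ± 1.00 in uninjured libraries, 19.9% ± 4.95 in IgG and 13.3% ± 2.42 in hENPP1mAb. Fibroblasts made up 32.7% ± 1.19, 35.3% ± 11.01 and 24.2% ± 3.16 in the same order. Endothelial nuclei made up 5.93% ± 1.06, 14.8% ± 3.77 and 22.7% ± 4.63. Endocardial nuclei made up 5.56% ± 0.658, 1.83% ± 0.267 and 3.08% ± 0.616, and mural nuclei (pericytes and smooth muscle) 4.96% ± 0.666, 3.87% ± 1.01 and 5.64% ± 0.443. Nuclei left without a class made up 7.69% in uninjured, 11.4% in IgG and 5.34% in hENPP1mAb libraries on average, and these are part of the denominator.

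**Figure D1:**
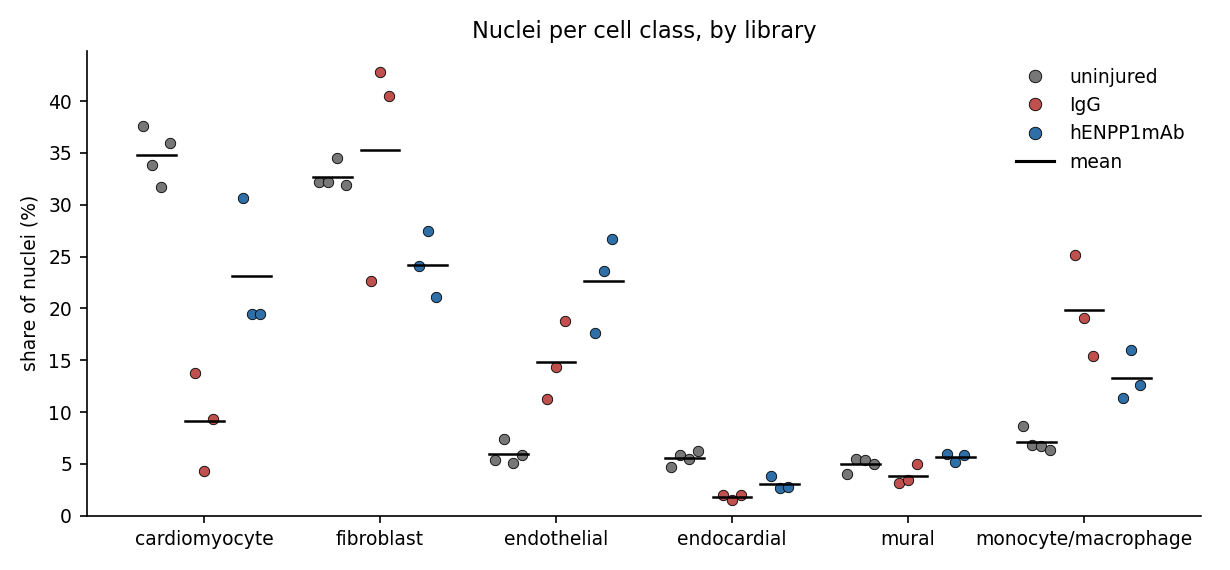
Share of nuclei per cell class in each library, in percent of all nuclei of the library, with 1 point per library and a line at the mean of each group. The cardiomyocyte share was 34.8% in uninjured, 9.14% in IgG and 23.2% in hENPP1mAb libraries on average.

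Across the 6 injured and 4 uninjured libraries, the cardiomyocyte share fell by 18.6 percentage points (exact permutation test, two-sided, adjusted p = 0.0214 over 6 classes). The endothelial share rose by 12.8 points and the monocyte and macrophage share by 9.45 points, and the endocardial share fell by 3.11 points (exact permutation, adjusted p = 0.0190 each). Fibroblast and mural shares differed by -2.91 and -0.208 points and did not pass (exact permutation, adjusted p = 0.674 and 0.733). With IgG alone as the injured group, the differences that passed were -25.7 points for cardiomyocytes, 8.86 for endothelial, -3.73 for endocardial and 12.7 for monocyte and macrophage nuclei (exact permutation, adjusted p = 0.0429 each). With any 1 of these 7 libraries left out the splits are too few for a p below 0.05, and none of these 4 passed (exact permutation, adjusted p = 0.08 to 0.15); the differences were then -28.0 to -23.2, 6.88 to 10.6, -4.02 to -3.50 and 10.1 to 14.97 points in the same order. These differences rest on which nuclei are counted: with at least 500 genes and at most 1% mitochondrial counts per nucleus the cardiomyocyte share fell by 55.1 points, while the injured fibroblast share was 19.3 points higher than the uninjured one and the endocardial share 0.125 points higher. With nuclei of at least 1100 UMIs the cardiomyocyte share fell by 43.1 points. Without uninjured 2, 3 or 4 the adjusted p for the monocyte and macrophage share was 0.0536, at 9.35, 9.32 and 9.19 points.

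Between the antibody groups, hENPP1mAb minus IgG, the mean cardiomyocyte share differed by 14.04 points, the endothelial share by 7.87, the mural share by 1.78 and the endocardial share by 1.25. The fibroblast share differed by -11.1 points and the monocyte and macrophage share by -6.57. Cardiomyocyte, endocardial and mural shares did not overlap between the 3 libraries of each group. None of the 6 differences passed the exact permutation test (two-sided, adjusted p = 0.2 to 0.3), and 3 against 3 libraries cannot give a p below 0.1. An edgeR test of nuclei numbers passed in all 6 classes, with log2 differences of 1.34 for cardiomyocytes (adjusted p = 3.5e-05) and of at most 0.75 in either direction for the others (adjusted p = 0.0233 to 0.0430).

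The comparison of IgG with uninjured libraries asks how infarction under the control antibody changed each class. In fibroblasts, Postn (periostin, a matrix protein of activated fibroblasts) rose from 23.7 ± 6.78 CPM (UMIs scaled to the library total with TMM factors; SD, n = 4) to 1613 ± 95.3 (n = 3), a log2 fold change of 6.09 ± 0.26 (SE, adjusted p = 6.8e-09). Col1a1 (type I collagen) rose from 126 ± 18.0 to 1328 ± 231 CPM and Acta2 (smooth muscle actin) from 2.93 ± 1.04 to 74.8 ± 20.3 CPM. Cthrc1 had 1 UMI in all uninjured fibroblasts together, and the ratio of its level in IgG to that was 1575 (95% counting interval 283 to 62203). Cemip (a hyaluronan-degrading protein) had 3 UMIs there, with a ratio of 4500 (1540 to 21823), and Spp1 (osteopontin) had 0, so that it was at least 153-fold higher in IgG against a floor of 3 counts over the group. In IgG libraries Spp1 stood at 41.3 CPM in fibroblasts, 57.4 over all nuclei and 167 in monocytes and macrophages. Free RNA, which is RNA from other nuclei, was estimated at 41.2% of IgG fibroblast counts, so part of this Spp1 may come from other classes. The 3 genes with the largest decreases were Tll2 (a metalloprotease), Col6a6 (a type VI collagen chain) and Necab1, at -5.69 ± 0.62, -5.56 ± 0.25 and -5.14 ± 0.21.

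Of the myofibroblast list, 21 of 23 measured genes rose and 2 fell in fibroblasts, and the same numbers held when adjusted over the list alone (camera adjusted p = 5.0e-23; adjusted p = 0.0358 with an estimated correlation). Runx1 (a transcription factor) reached 5.66 and Actn1 (alpha-actinin) 4.82 on the log2 scale. Of 40 genes for extracellular matrix and collagens, 29 rose and 6 fell, and 29 and 7 when adjusted over the list alone (camera adjusted p = 4.3e-15; adjusted p = 0.0512 with an estimated correlation). Of 35 cell cycle genes, 33 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 3.8e-07; adjusted p = 0.433 with an estimated correlation). Matrifibrocyte genes, a set described for scar fibroblasts, rose in 11 and fell in 1 of 13, the same as when adjusted over the list alone (camera adjusted p = 5.7e-05; adjusted p = 0.243 with an estimated correlation). Targets of p53 rose in 15 of 22, also when adjusted over the list alone (camera adjusted p = 0.000216; adjusted p = 0.201 with an estimated correlation), among them Mdm2 at 1.32 and Cdkn1a, the cell cycle inhibitor p21, at 1.94 ± 0.28. Genes of oxidative phosphorylation fell in 52 of 56, the same as when adjusted over the list alone (camera adjusted p = 8.9e-14; adjusted p = 0.224 with an estimated correlation). All 13 mitochondrially encoded genes fell, also when adjusted over the list alone (camera adjusted p = 8.9e-26; adjusted p = 0.0658 with an estimated correlation). Mitochondrially encoded genes took 1.11% of all UMIs in uninjured and 0.0778% in IgG libraries.

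In cardiomyocytes, genes of the fetal and border-zone list rose in 16 and fell in 1 of 18, the same as when adjusted over the list alone (camera adjusted p = 7.1e-11; adjusted p = 0.0106 with an estimated correlation). Nppa (atrial natriuretic peptide) rose from 5.68 ± 4.35 CPM (n = 4) to 110 ± 81.6 (n = 3), a log2 fold change of 4.26 ± 0.67 (adjusted p = 0.000346). Nppb rose by 2.29 ± 0.44, Ankrd1 (a stress-induced ankyrin-repeat protein) by 2.88 ± 0.30 and Myh7 (the slow myosin heavy chain) by 1.38 ± 0.17. Cdkn1a rose by 3.54 ± 0.39 and Gdf15 (a stress-induced secreted factor) by 4.06 ± 0.72. Genes of oxidative phosphorylation fell in 49 of 56, and in 51 when adjusted over the list alone (camera adjusted p = 8.9e-13; adjusted p = 0.112 with an estimated correlation). P2ry14 (a receptor for UDP sugars), Fndc9 and Kif28 fell most, at -5.09, -4.32 and -4.28 on the log2 scale. Matrix genes rose in 38 of 39 and fell in 1, also when adjusted over the list alone (camera adjusted p = 2.1e-41; adjusted p = 0.0195 with an estimated correlation). Cemip, Postn and Fn1 led the increases. The estimate of free RNA, which is RNA from other nuclei in the droplet, covered 100% of the counts of these 3 genes in cardiomyocytes, and fibroblast markers there stood at 650 ± 106 CPM in IgG and 346 ± 70.5 in uninjured libraries.

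In monocytes and macrophages, the resident macrophage list fell in 12 and rose in 1 of 16, the same as when adjusted over the list alone (camera adjusted p = 3.0e-08; adjusted p = 0.175 with an estimated correlation). Timd4 fell from 114 ± 25.8 to 1.53 ± 0.679 CPM, Lyve1 from 54.1 ± 19.0 to 5.89 ± 4.34 and Mgl2 from 89.0 ± 14.1 to 0.545 ± 0.546. Ccr2 (a chemokine receptor of monocytes) fell by 2.24 ± 0.49 (adjusted p = 0.0066). The list of Spp1 and Trem2 lipid-handling macrophages rose in 16 and fell in 1 of 21, and in 17 and 2 when adjusted over the list alone (camera adjusted p = 3.0e-16; adjusted p = 0.0371 with an estimated correlation). Gpnmb rose from 2.07 ± 1.83 to 608 ± 53.2 CPM and Trem2 by 1.63 ± 0.36 on the log2 scale. Spp1 had 1 UMI in the uninjured group of this class, with a ratio of 436 (78.2 to 17211). Bank1, which also stands in the B cell marker list, fell from 737 ± 204 to 17.6 ± 2.15 CPM. Clusters named as B or as T and NK cells held 0 nuclei in each uninjured library, against 0 to 83 and 43 to 135 nuclei per IgG library, so any such cells were not separated from this class in uninjured libraries, and the falls in it are not shown to lie in macrophages alone.

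Matrix genes rose in 36 of 39 in endothelial, 32 of 37 in endocardial and 30 of 39 in mural nuclei and fell in 1 in each; adjusted over the list alone the rises numbered 36, 33 and 31. The camera adjusted p was 1.9e-36, 2.0e-35 and 7.2e-24, and the adjusted p with an estimated correlation 0.0371, 0.0195 and 0.0516. TGF-beta response genes rose in 15 of 19 in mural nuclei, and in 16 when adjusted over the list alone (camera adjusted p = 1.9e-15; adjusted p = 0.0106 with an estimated correlation). In endothelial nuclei, Aqp7 (a water and glycerol channel) fell from 121 ± 23.2 to 5.82 ± 1.78 CPM and Cobl fell by 4.46 on the log2 scale. In endocardial nuclei, Lsamp (a cell adhesion protein) fell from 744 ± 212 to 9.55 ± 5.25 CPM, and Pcdh11x (a protocadherin) was at least 63.3-fold higher in IgG. In mural nuclei, Actg2 (enteric smooth muscle actin) was at least 53.6-fold higher in IgG, and the list of mural markers fell in 7 of 8, also when adjusted over the list alone (camera adjusted p = 1.3e-06). Fibroblast markers in endothelial nuclei stood at 2628 ± 354 CPM in IgG and 1032 ± 231 in uninjured libraries, and fibroblast markers in mural nuclei at 3635 ± 689 and 2639 ± 877, where the mural markers together stood at 3255 ± 311 and 8562 ± 873. Free RNA was estimated at 59.0% of endothelial, 66.35% of endocardial and 53.4% of mural counts in IgG and at 36.3%, 39.9% and 41.1% in uninjured libraries.

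In the edgeR test of IgG against uninjured libraries, 3396 genes rose and 3548 fell of 14316 tested in cardiomyocytes, and 4284 rose and 3975 fell of 14295 in fibroblasts. The counts were 2208 and 2061 of 12663 in endothelial, 1225 and 1045 of 7732 in endocardial, 1404 and 1408 of 9074 in mural, and 1922 and 1859 of 11697 in monocyte and macrophage nuclei. The libraries of the 2 groups did not overlap for 36.3% to 58.9% of the genes tested in a class, where chance gives 5.71%. Genes called with most of their counts estimated as free RNA made up 15.01% of the calls in fibroblasts, 17.5% in cardiomyocytes and 37.1% to 40.6% in the other classes, where such genes made up 15.9%, 12.96% and 37.3% to 44.3% of those tested. Of 154 list tests, 92 passed, and 23 of these kept their call with an estimated correlation. Some splits that mix the groups called as many lists, so the number that passed says little about injury. The labels give no batch, and the uninjured libraries also differed from the injured ones in depth per nucleus and mitochondrial share, so a batch cannot be told apart from injury. With at least 500 genes and at most 1% mitochondrial counts per nucleus, the total called was 1431 in endothelial nuclei (1116 up and 315 down) and 5404 in fibroblasts (3047 and 2357), against 4269 and 8259.

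The comparison of hENPP1mAb with IgG asks what the antibody against ENPP1 changed in infarcted tissue. In fibroblasts, Col1a1 fell from 1328 ± 231 CPM (SD, n = 3) to 593 ± 113 (n = 3), a log2 fold change of -1.16 ± 0.16 (SE, adjusted p = 0.000323), and Cthrc1 from 148 ± 27.4 to 46.1 ± 15.7 CPM. Acta2 fell by 1.96 ± 0.38 (adjusted p = 0.00497) and Lox (a collagen-crosslinking enzyme) by 1.97 ± 0.15 (adjusted p = 5.2e-06). In cardiomyocytes, Myh7 fell from 1161 ± 125 to 412 ± 101 CPM and Ankrd1 from 2012 ± 635 to 602 ± 211. In monocytes and macrophages, the resident markers Timd4, Lyve1 and Folr2 rose by 3.11 ± 0.41, 2.78 ± 0.40 and 2.92 ± 0.50, and Spp1 fell by 1.09 ± 0.24 (adjusted p = 0.0170). Without IgG 3 or hENPP1mAb 2, Spp1 differed by -0.90 and -0.85 and was not called (adjusted p = 0.0716 and 0.0909).

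**Figure D2:**
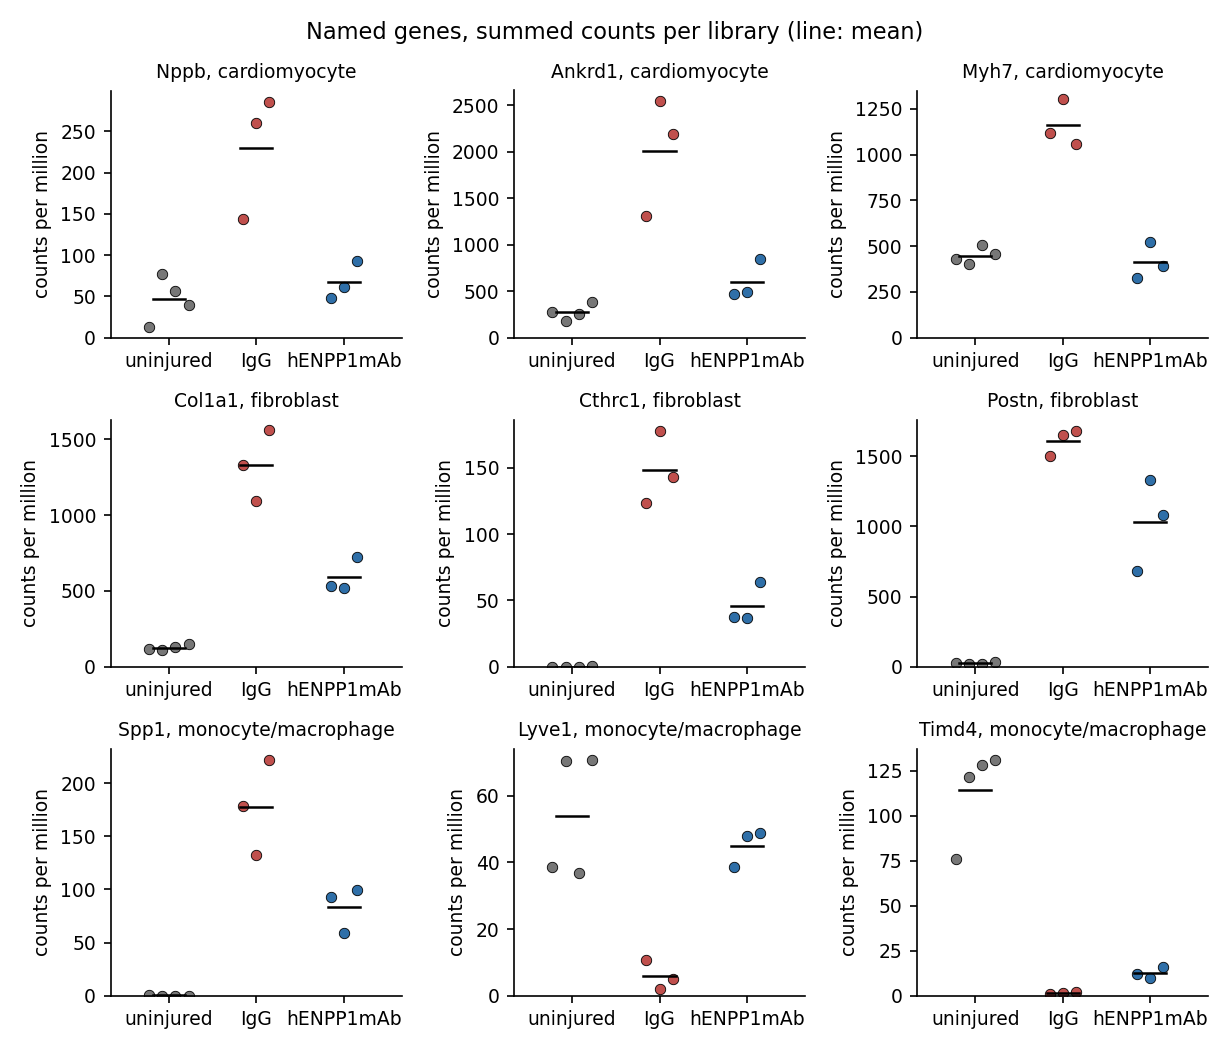
CPM of 9 named genes in cardiomyocytes, fibroblasts or monocytes and macrophages, with 1 point per library and a line at the mean of the uninjured, IgG and hENPP1mAb groups. Mean Myh7 in cardiomyocytes was 448 CPM in uninjured, 1161 in IgG and 412 in hENPP1mAb libraries.

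The genes with the largest increases in fibroblasts were Ppl (periplakin) at 4.51 ± 0.63 (adjusted p = 0.00155), Hmcn2 (hemicentin 2, a matrix protein) at 3.59 ± 0.54 (582 ± 100 against 48.7 ± 41.9 CPM) and Tll2 at 3.48 ± 0.65. Scel, Hs6st2 (a heparan sulfate sulfotransferase) and Prag1 fell most, at -3.01, -2.49 and -2.38. Of 23 myofibroblast genes, 17 fell and none rose, and 19 fell when adjusted over the list alone (camera adjusted p = 2.0e-13; adjusted p = 0.0673 with an estimated correlation). Postn, a member, differed by -0.64 ± 0.23 (adjusted p = 0.0546; 1033 ± 326 against 1613 ± 95.3 CPM) and was not called, but passed without hENPP1mAb 2 (-0.84, adjusted p = 0.0263). Of 40 matrix genes, 26 fell and 5 rose, and 27 and 5 when adjusted over the list alone (camera adjusted p = 1.2e-10; adjusted p = 0.102 with an estimated correlation). TGF-beta response genes fell in 9 and rose in 1 of 21, and in 12 and 1 when adjusted over the list alone (camera adjusted p = 0.00313; adjusted p = 0.0861 with an estimated correlation). Ccn2 (connective tissue growth factor) fell by 1.29 ± 0.22, and Ltbp1, which binds latent TGF-beta, rose by 1.00 ± 0.14. Cell cycle genes fell in 16 of 35, and in 18 when adjusted over the list alone (camera adjusted p = 2.8e-06; adjusted p = 0.387 with an estimated correlation). Fibroblast markers within the class stood at 5313 ± 1143 CPM in hENPP1mAb and 6968 ± 438 in IgG libraries, and cardiomyocyte markers there at 7669 ± 2622 and 2033 ± 1044.

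Lists close to the substrates and products of ENPP1 were tested in every class. In fibroblasts, genes of purinergic signalling and ectonucleotidases rose in 8 and fell in 2 of 24, and in 9 and 2 when adjusted over the list alone (camera adjusted p = 0.00323; adjusted p = 0.129 with an estimated correlation). P2ry1 (an ADP receptor) rose from 0.692 ± 0.140 to 7.28 ± 1.14 CPM, and Entpd2 (an ectonucleotidase that cleaves ATP) from 14.6 ± 1.22 to 47.0 ± 17.7. Ada (adenosine deaminase) fell from 17.02 ± 11.2 to 4.06 ± 0.556. The list also rose in mural nuclei, in 5 of 14 (also 5 when adjusted over the list alone; camera adjusted p = 0.0301; adjusted p = 0.165 with an estimated correlation), with P2ry14 at 1.68 ± 0.23 and Slc29a1 (a nucleoside transporter) at 1.68 ± 0.31. Cardiomyocyte markers in mural nuclei stood at 10835 ± 5967 CPM in hENPP1mAb and 2686 ± 1025 in IgG libraries, and free RNA was estimated at 61.4% and 53.4% of mural counts. That estimate was 79.45% in hENPP1mAb 1 but 53.2% and 51.5% in hENPP1mAb 2 and 3, so its order between the groups rests on 1 library. Genes of pyrimidine synthesis and salvage fell in 9 and rose in 2 of 22 in fibroblasts, also when adjusted over the list alone (camera adjusted p = 0.0181; adjusted p = 0.220 with an estimated correlation), with Tyms (thymidylate synthase) at -1.36 and Ctps (CTP synthase) at -1.14. Tyms and Rrm2 also stand in the cell cycle list, which fell in fibroblasts too, so the falls of these lists are not independent. Targets of p53 fell in 5 and rose in 1 of 22 in fibroblasts, the same as when adjusted over the list alone (camera adjusted p = 0.0126; adjusted p = 0.318 with an estimated correlation). Cdkn1a was not called in any class where it was tested, with log2 differences from -0.74 ± 0.55 in endocardial nuclei to 0.01 ± 0.32 in monocytes and macrophages. In cardiomyocytes, the purinergic, pyrimidine and p53 lists did not pass (camera adjusted p = 0.498, 0.364 and 0.0689).

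Cardiomyocyte genes of the fetal and border-zone list fell in 7 and rose in 1 of 18, and in 9 and 1 when adjusted over the list alone (camera adjusted p = 9.1e-05; adjusted p = 0.0644 with an estimated correlation). Nppb fell by 1.77 ± 0.47 (adjusted p = 0.0155), a call that ended without IgG 3, hENPP1mAb 1 or hENPP1mAb 2 (-1.57, -1.57 and -1.71; adjusted p = 0.0518, 0.0723 and 0.0710), while Nppa stood at 42.4 ± 25.5 against 110 ± 81.6 CPM and was not called (adjusted p = 0.140). Genes of oxidative phosphorylation rose in 41 of 56 and none fell, and 48 rose when adjusted over the list alone (camera adjusted p = 5.4e-15; adjusted p = 0.11 with an estimated correlation), with Cyc1 (cytochrome c1) at 1.63 ± 0.21 and Ndufv1 (a subunit of complex I) at 1.69 ± 0.24. The mitochondrially encoded share of all UMIs was 0.106% to 0.137% in hENPP1mAb and 0.0532% to 0.101% in IgG libraries, and cardiomyocyte markers within the class stood at 87988 ± 2514 and 61780 ± 7672 CPM. Genes of fatty acid oxidation rose in 7 and fell in 1 of 32, also when adjusted over the list alone (camera adjusted p = 0.0180; adjusted p = 0.440 with an estimated correlation). Ces1d (a carboxylesterase), Ptgds (prostaglandin D synthase) and Gbp6 had the largest increases, at 4.18 ± 0.50, 2.71 ± 0.41 and 2.37 ± 0.33. TGF-beta response genes fell in 14 of 20 and none rose, and 14 fell and 1 rose when adjusted over the list alone (camera adjusted p = 1.5e-07; adjusted p = 0.0245 with an estimated correlation), with Tgfb2 at -2.17 ± 0.25. Matrix genes fell in 36 of 39, and in 37 when adjusted over the list alone (camera adjusted p = 3.3e-38; adjusted p = 0.0245 with an estimated correlation). Free RNA could give most of the counts of 34 of the 39. Fibroblast markers in cardiomyocytes stood at 176 ± 19.4 CPM in hENPP1mAb and 650 ± 106 in IgG libraries. Ncam1, the neural cell adhesion molecule, fell by 2.98 ± 0.22 with 31.1% of its counts estimated as free RNA.

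The resident macrophage list rose in 5 of 16 in monocytes and macrophages, and in 11 when adjusted over the list alone (camera adjusted p = 1.8e-11; adjusted p = 0.152 with an estimated correlation). Mgl2 had the largest increase, from 0.545 ± 0.546 to 23.7 ± 10.4 CPM, and Cbr2 rose from 4.89 ± 2.52 to 81.6 ± 38.9. The list of Spp1 and Trem2 lipid-handling macrophages fell in 8 and rose in 1 of 21, and in 12 and 1 when adjusted over the list alone (camera adjusted p = 1.6e-05; adjusted p = 0.169 with an estimated correlation). Gpnmb fell from 608 ± 53.2 to 306 ± 66.1 CPM (adjusted p = 0.0155). Trem2 and Ccr2 differed by 0.55 ± 0.31 and 1.13 ± 0.50 and were not called (adjusted p = 0.280 and 0.188); Ccr2 passed without IgG 1 (1.91, adjusted p = 0.0278). Rgs1, a regulator of G-protein signalling, fell from 61.0 ± 29.9 to 7.30 ± 3.83 CPM (adjusted p = 0.0184). The call for Gpnmb ended without IgG 2, hENPP1mAb 2 or hENPP1mAb 3 (-0.93, -0.82 and -0.99; adjusted p = 0.0554 to 0.0902), and that for Rgs1 without any of IgG 2, IgG 3 and the 3 hENPP1mAb libraries (-2.63 to -3.53; adjusted p = 0.0520 to 0.0826). Interferon response genes rose in 3 of 28, and in 6 when adjusted over the list alone (camera adjusted p = 0.0337; adjusted p = 0.576 with an estimated correlation), with Oas2 (an antiviral enzyme) at 1.67 ± 0.25. None of 16 inflammatory cytokine and NF-kB genes was called, also when adjusted over the list alone (camera adjusted p = 0.298). Clusters named as B or as T and NK cells held 0 nuclei in hENPP1mAb 2, and those named as B held 0 in hENPP1mAb 1 and IgG 3. At Leiden resolution 2 the monocyte and macrophage class held 927 nuclei in hENPP1mAb 2, against 1574 at resolution 1. The changes in this class are thus not shown to lie in macrophages alone. Marker levels within this class also differed between the groups: in hENPP1mAb, IgG and uninjured libraries its own markers stood at 3608 ± 1245, 1704 ± 826 and 8408 ± 1707 CPM, fibroblast markers at 1325 ± 364, 2787 ± 237 and 1322 ± 243, and cardiomyocyte markers at 10933 ± 3671, 3244 ± 1918 and 6713 ± 6044.

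In mural nuclei, Pde4c (a phosphodiesterase for cyclic AMP) rose from 7.72 ± 1.31 to 183 ± 43.8 CPM, and Actg2 fell from 115 ± 66.1 to 6.64 ± 7.49 (adjusted p = 0.0198). Without IgG 3 or hENPP1mAb 3, Actg2 differed by -4.19 and -3.76 and was not called (adjusted p = 0.0706 and 0.0910). The list of mural markers rose in 7 of 8, also when adjusted over the list alone (camera adjusted p = 8.8e-09). TGF-beta response genes fell in 12 of 19 mural genes, and in 14 when adjusted over the list alone (camera adjusted p = 5.3e-13; adjusted p = 0.0245 with an estimated correlation). Fibroblast markers in mural nuclei fell as well, from 3635 ± 689 CPM in IgG to 1409 ± 353 in hENPP1mAb libraries. In endothelial nuclei, Grin2a (a glutamate receptor subunit) fell from 67.0 ± 44.6 to 5.21 ± 0.946 CPM and Cdkn1c (a cell cycle inhibitor) rose by 2.22 ± 0.36. Matrix genes fell in 31 of 39 endothelial, 26 of 37 endocardial and 25 of 39 mural genes, and in 33, 31 and 28 when adjusted over the list alone, where 2 mural genes rose. The camera adjusted p was 3.5e-31, 3.5e-31 and 2.1e-25, and the adjusted p with an estimated correlation 0.0644, 0.0245 and 0.0644. Sarcomere and calcium handling genes, which belong to cardiomyocytes, rose in 15 of 30 endothelial and 15 of 30 fibroblast genes, and in 24 and 19 when adjusted over the list alone (camera adjusted p = 6.0e-13 and 3.4e-10; adjusted p = 0.221 and 0.290 with an estimated correlation). Free RNA could give most of the counts of 29 and 30 of these. Cardiomyocyte markers in fibroblasts stood at 7669 ± 2622 CPM in hENPP1mAb, 2033 ± 1044 in IgG and 2659 ± 395 in uninjured libraries, fibroblast markers in endothelial nuclei at 846 ± 81.4, 2628 ± 354 and 1032 ± 231, and fibroblast markers in endocardial nuclei at 1014 ± 43.8, 3275 ± 107 and 1881 ± 334.

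**Figure D3:**
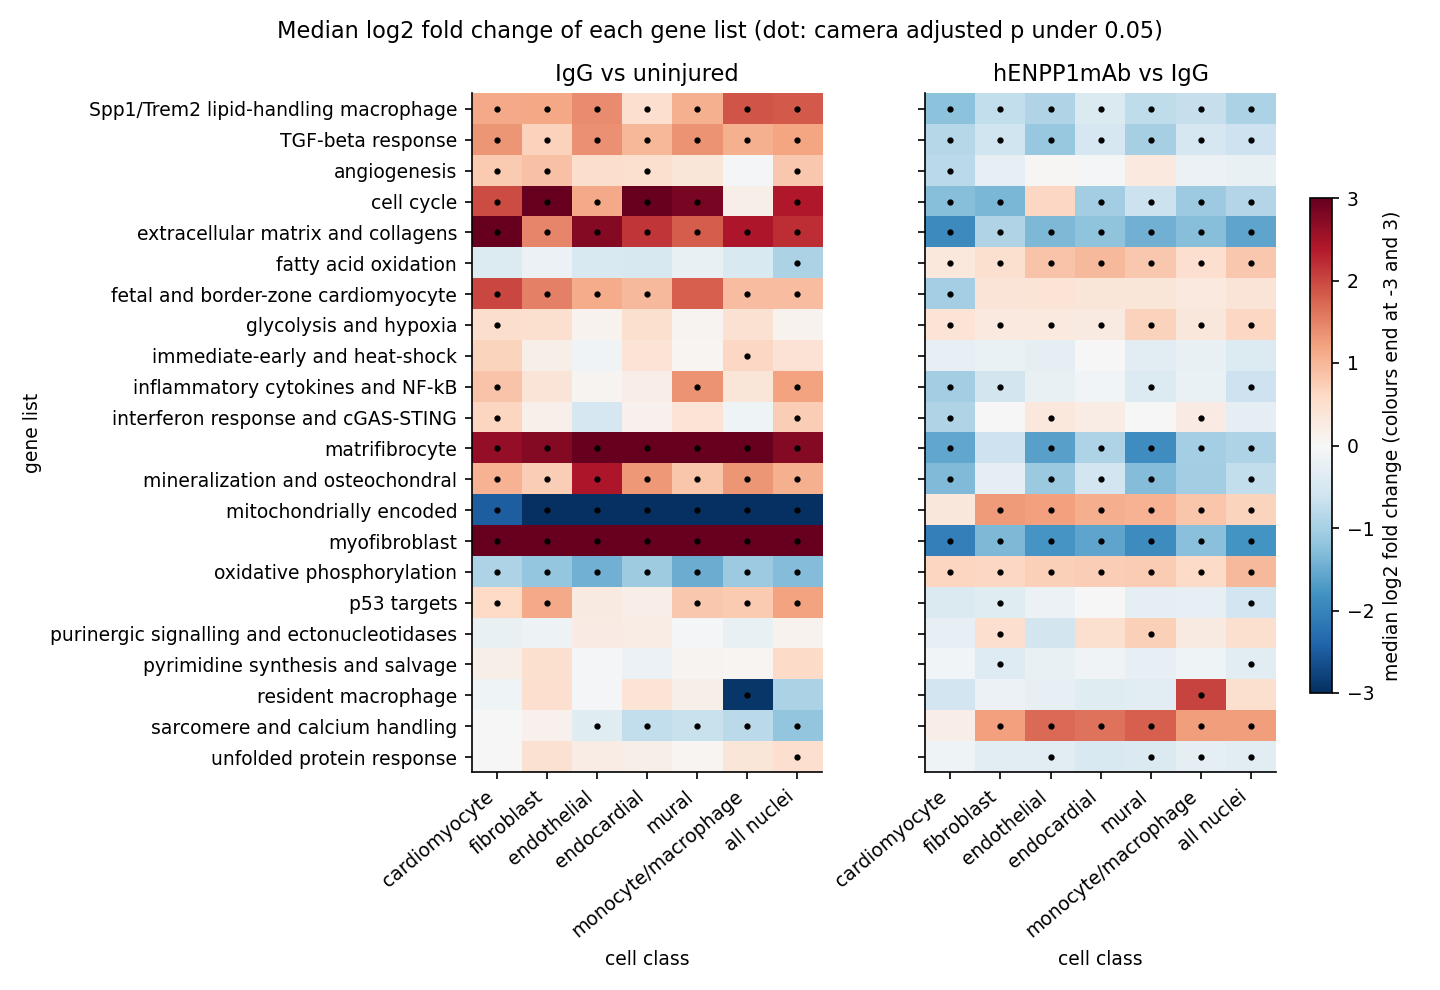
Median log2 fold change of each of 22 fixed gene lists (vertical axis) in the 6 classes and all nuclei together (horizontal axis), as a colour from lower (blue) to higher (red), with a dot where the list passed camera, for IgG against uninjured (left) and hENPP1mAb against IgG (right). The matrix list was higher in IgG than in uninjured libraries and lower in hENPP1mAb than in IgG libraries in all 6 classes.

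In the edgeR test of hENPP1mAb against IgG, 1782 genes rose and 2030 fell of 14316 tested in cardiomyocytes, and 1854 rose and 2020 fell of 14295 in fibroblasts. The counts were 1283 and 1140 of 12663 in endothelial, 410 and 350 of 7732 in endocardial, 794 and 660 of 9074 in mural, and 466 and 444 of 11697 in monocyte and macrophage nuclei. The libraries of the 2 groups did not overlap for 27.1% to 38.9% of the genes tested in a class, where chance gives 10%. Genes called with most of their counts estimated as free RNA made up 25.9% of the calls in cardiomyocytes against 12.96% of the genes tested, 20.5% against 15.9% in fibroblasts, 48.3% against 37.3% in endothelial, 52.0% against 42.7% in endocardial, 40.7% against 38.6% in mural and 40.55% against 44.3% in monocyte and macrophage nuclei. Of 154 list tests, 98 passed, and 6 of these kept their call with an estimated correlation. Another split of the same libraries called nearly as many lists, so the number that passed says little about the antibody. The total called in monocytes and macrophages, 910, was 290 without IgG 2, 392 without IgG 3, 287 without hENPP1mAb 2 and 233 without hENPP1mAb 3, and 1766 with clusters at Leiden resolution 2. Totals were 2300 in fibroblasts and 478 in endocardial nuclei without hENPP1mAb 2, 1590 in endothelial nuclei without IgG 2, and 905 and 962 in mural nuclei without IgG 3 and without hENPP1mAb 3, against 3874, 760, 2423 and 1454 with all libraries.

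**Figure D4:**
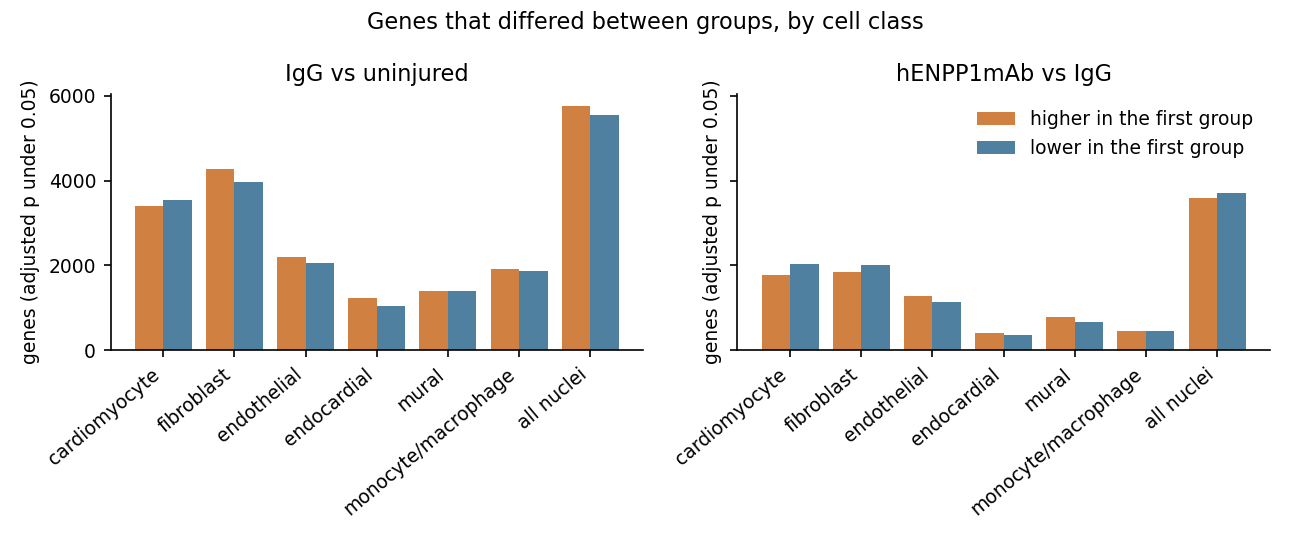
Number of genes called higher or lower (vertical axis, bars) in the 6 classes and in all nuclei together (horizontal axis) in the edgeR tests of IgG against uninjured (left) and hENPP1mAb against IgG libraries (right). The hENPP1mAb comparison called 3812 genes in cardiomyocytes and 910 in monocytes and macrophages.

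The relation between the comparisons asks whether genes moved by infarction stood closer to the uninjured level in the antibody group. In cardiomyocytes, 1405 of the 3396 genes higher in IgG than in uninjured libraries were lower in hENPP1mAb than in IgG, and 214 were higher. Of the 3548 genes lower after infarction, 844 were higher and 87 lower in hENPP1mAb. In fibroblasts, 1299 of 4284 genes were higher after infarction and then lower, and 235 higher in both. With unrelated lists of these sizes, 482 cardiomyocyte and 605 fibroblast genes would be higher and then lower, but both comparisons share the IgG libraries. Fibroblast markers in cardiomyocytes were also higher and then lower. They stood at 282 to 438 CPM in uninjured, 573 to 771 in IgG and 153 to 188 in hENPP1mAb libraries. The relation was not run on genes low in free RNA, so the part of free RNA in it was not tested. Across genes, Pearson's r between the log2 fold changes was -0.56 in cardiomyocytes, -0.51 in fibroblasts, -0.52 in endothelial, -0.49 in endocardial, -0.61 in mural, and -0.48 in monocyte and macrophage nuclei. Counts simulated with no antibody effect gave a mean r from -0.21 in cardiomyocytes to -0.08 in fibroblasts, since the IgG libraries enter both fold changes. The simulations drew each gene on its own, so shifts that many genes share between libraries are not in them. They set no bound on the r that such shifts would give. Another split of the 6 injured libraries gave -0.43 in cardiomyocytes, and another -0.44 in endothelial nuclei. In monocytes and macrophages another split gave a stronger negative r than the real one. With the injury effect taken from the mean of both injured groups, r was -0.31, -0.29, -0.28, -0.17, -0.34 and -0.22 in the same order, against simulated means of -0.078 to 0.024. Genes are not independent replicates, so no p is given for r.

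Enpp1 itself lies on chromosome 10 of the mouse genome (GRCm38), from 24637914 to 24712159 on the minus strand. Its log2 difference between hENPP1mAb and IgG was -1.18 ± 1.27 in fibroblasts (adjusted p = 0.531), the class with the highest mean Enpp1 level of the 6, and -2.34 ± 0.81 in cardiomyocytes (adjusted p = 0.0496; 1.28 against 5.78 CPM, with 67.1% of counts estimated as free RNA). Leaving out any injured library except IgG 2 ended the cardiomyocyte call, with differences from -2.87 to -0.95 (adjusted p = 0.0684 to 0.447). In endothelial, mural and monocyte and macrophage nuclei it was -1.46, -1.54 and -1.04 and not called (adjusted p = 0.432, 0.433 and 0.632). Between IgG and uninjured libraries, Enpp1 was not called in any of these 5 classes (log2 differences from -0.70 to 3.18, adjusted p = 0.258 to 0.672), though without IgG 3 the cardiomyocyte difference was -2.09 (adjusted p = 0.0382). The injured libraries differed widely within each group. Fibroblast Enpp1 stood at 40.9, 2.47 and 199.5 CPM in IgG 1, 2 and 3, and at 1.67, 56.9 and 47.97 CPM in hENPP1mAb 1, 2 and 3. The 4 uninjured libraries held 44.2 to 54.2 CPM. Mouse Enpp1 transcripts were counted against the mouse genome, and the deposited features hold 0 entries for the human gene.

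**Figure D5:**
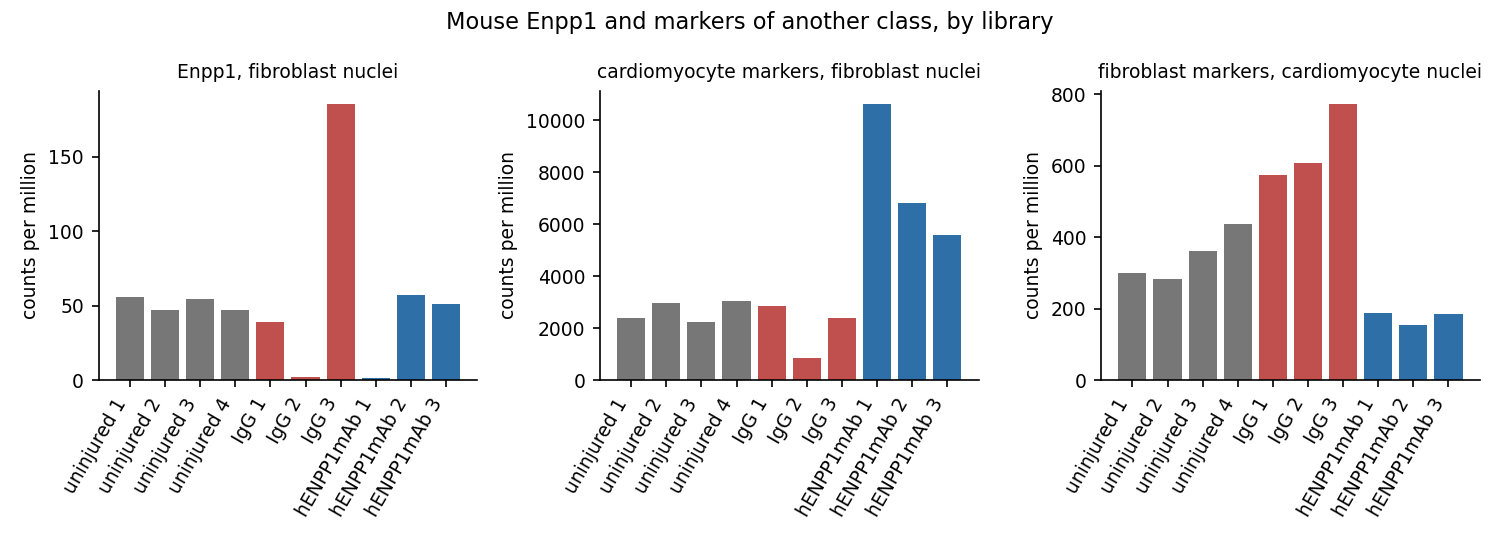
CPM without TMM factors in each of the 10 libraries (bars) of Enpp1 in fibroblast nuclei, of cardiomyocyte markers in fibroblast nuclei and of fibroblast markers in cardiomyocyte nuclei. Enpp1 was 2.40 CPM in IgG 2 and 1.49 CPM in hENPP1mAb 1, against 47.1 to 55.7 CPM in the uninjured libraries.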

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

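Of the tests on Enpp1, those of counting noise, of fibroblast numbers and of a humanized allele were chosen only after the result was seen; the test of neighbouring genes and the 3 tests on folds shared between classes were not.

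In 111 values of the 4 uninjured libraries, 12 had 1 library far from the other 3 by Dixon's test, which takes its gap to the nearest of them as a part of the whole range. Chance gives this in about 1 of 20 such groups. The fibroblast share was 34.5% in uninjured 3 and 31.9% to 32.2% in the others (gap 0.889 of the range). Among markers of other classes, mural markers in cardiomyocytes stood at 535 CPM in uninjured 2 against 462 to 468 (0.927), and cardiomyocyte markers in monocytes and macrophages at 15741 CPM in uninjured 1 against 2956 to 4260 (0.898). Endothelial markers in mural nuclei stood at 1630 CPM in uninjured 3 against 536 to 668 (0.880), and monocyte and macrophage markers in mural nuclei at 752 CPM in uninjured 1 against 161 to 212 (0.913). Among named genes in fibroblasts, Entpd2 was 67.5 CPM in uninjured 1 against 90.6 to 94.2 (0.865), Ada 1.98 CPM in uninjured 2 against 1.09 to 1.16 (0.930), and Ltbp1 608 CPM in uninjured 2 against 525 to 537 (0.849). Timd4 in monocytes and macrophages was 76.0 CPM in uninjured 1 against 122 to 131 (0.831). Cthrc1 and Cemip in fibroblasts were counted only in uninjured 4, at 0.365 and 1.09 CPM, and Spp1 in monocytes and macrophages only in uninjured 1, at 1.07 CPM (gap 1 of the range for each). With 1 to 3 UMIs in 1 library and 0 in the others the gap is always 1, so these 3 of the 12 say nothing about a library.

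The log2 fold changes between hENPP1mAb and IgG resembled each other between cell classes, with a mean r across genes of 0.675 over 15 pairs of classes (0.537 to 0.783). Over genes of which free RNA could give at most 0.5 of the counts in both classes (2790 to 9379 genes per pair), the mean r was 0.578, where free RNA as the cause was set in advance to bring it below 0.5 of the value for all genes. It was 0.671 after a trend on gene span was taken out in each class, where 99.9% of genes had a span and Spearman's rho of fold with span lay between -0.269 and -0.109, and 0.640 with nuclei thinned to at most 1000 UMIs. The value without the span trend argues against gene length as the whole cause. The genes kept as low in free RNA could still owe up to 0.5 of their counts to it. Their mean r thus cannot decide on free RNA, which stays open. Random thinning keeps the expected gene proportions of each nucleus, so its value cannot decide on depth, which stays open. A response shared by the cell classes and a difference in handling between the groups of libraries were not tested and stay open, as does the spread between the 3 libraries of each group.

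Mouse Enpp1 was near 0 in IgG 2 and hENPP1mAb 1, which are 1 library of each antibody group. Fibroblasts of these libraries held 17 and 7 Enpp1 UMIs (95% counting intervals 9.90 to 27.2 and 2.81 to 14.4), where the median rate of the other 8 libraries gives 375 and 249, which argues against counting noise. The level within fibroblasts was at most 0.0454 of that median, which argues against fewer fibroblasts as the cause. The 10 nearest expressed genes had a median ratio of 0.792 in these libraries, just under the bound of 0.8 set in advance. By that bound the test cannot decide on a loss over the region. The lowest ratio was 0.463, over 10 times the highest ratio of Enpp1, a comparison that was not set in advance. None of the 10 genes was thus as low as Enpp1, but a smaller loss over the region stays open. A humanized allele whose reads are not counted as mouse Enpp1 cannot be told apart from lower expression, since the deposited features hold 0 entries for the human gene, and the label gives all 10 libraries the same genotype.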

How the results depend on the processing

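The alternatives with at least 1100 UMIs per nucleus, with genes of which free RNA could give at most 0.5 of the counts, and with named nuclei as denominator were chosen only after the results were seen; the others were planned. The causes of the changes below were not tested, except that fewer genes or libraries enter some of them by construction. RLE scaling, DESeq2 and doublets kept left the total of genes called within 1.5 times in each class and comparison. Calls of single genes changed more: of 443 named gene and class pairs for hENPP1mAb against IgG, the call ended in 39 with nuclei of at least 1100 UMIs, 31 with the stricter filter, 18 with thinning, 17 with the replicate block, 16 with doublets kept, 16 with only the 2 groups, 12 with DESeq2, 10 with no low-count filter and 6 with Leiden resolution 2, and 2 to 14 pairs were newly called under each of these. Over the 6 injured libraries left out in turn, calls ended 225 times. With only genes low in free RNA, 164 pairs kept their verdict, 4 were newly called and the others could not be tested. Of 404 pairs for IgG against uninjured, the call ended in 19 with the stricter filter and 10 with at least 1100 UMIs. It ended in at most 4 under the other settings just named, and 25 times over the 7 libraries left out in turn. Some pairs could not be tested under a setting and are in none of these counts. With at least 1100 UMIs 333 of the 404 kept their verdict, and with thinning 368. For hENPP1mAb against IgG, 390 of the 443 kept it with thinning. The labels number the libraries but do not say whether the numbers pair them. Same-numbered hENPP1mAb and IgG libraries resembled each other at r from 0.08 to 0.26 over all nuclei. Of the 3 hENPP1mAb libraries, 2 resembled the same-numbered IgG library most over all nuclei, and 1 or 2 did in each class. A pairing is neither shown nor excluded, so the replicate block below is an alternative only.

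For hENPP1mAb against IgG, genes called numbered 2421 in cardiomyocytes, 1423 in endothelial and 433 in endocardial nuclei over genes low in free RNA; 2163 in cardiomyocytes, 2085 in fibroblasts and 4759 in all nuclei with only the libraries of the 2 groups; 2034 and 2289 in cardiomyocytes and fibroblasts with the replicate block; and 1646 and 872 in cardiomyocytes and mural nuclei with nuclei thinned to 1000 UMIs. The stricter filter on nuclei gave 427 in endocardial and 442 in monocyte and macrophage nuclei, nuclei of at least 1100 UMIs 448 and 346, and Leiden resolution 2 and no low-count filter 1766 and 1647 in monocytes and macrophages. Leaving out each library gave 2606 to 3946 in cardiomyocytes, 2300 to 4138 in fibroblasts, 1590 to 2867 in endothelial, 478 to 681 in endocardial, 905 to 1436 in mural and 233 to 980 in monocyte and macrophage nuclei, and 5844 to 8095 in all nuclei.

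For IgG against uninjured, the stricter filter gave 5404 in fibroblasts, 1431 in endothelial, 1197 in endocardial, 1507 in mural and 2409 in monocyte and macrophage nuclei. Nuclei of at least 1100 UMIs gave 1502 in endocardial, 1303 in mural and 2501 in monocyte and macrophage nuclei, thinning gave 3895 in cardiomyocytes and 1336 in endocardial nuclei, genes low in free RNA 1460 in endocardial nuclei, and the replicate block 2116 in monocytes and macrophages. With each library left out, all counts were within 1.5 times (5897 to 6798 in cardiomyocytes, 7334 to 8422 in fibroblasts). Lists called numbered 6 and 23 with an estimated correlation for the antibody and the injury comparison, 151 for injury with fry in either direction, and 91 to 110 and 87 to 93 with each library left out. The resident macrophage list in endothelial nuclei was not called between the antibody groups (down, camera adjusted p = 0.947), and without IgG 1 it turned to higher (adjusted p = 0.00764; 0.00764 to 0.988 with each library left out).

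For injured against uninjured shares, the stricter filter gave 19.3 points for fibroblasts (exact permutation, adjusted p = 0.00714), 0.125 for endocardial and 2.32 for mural nuclei, and nuclei of at least 1100 UMIs gave 13.9 for fibroblasts, 3.20 for mural and -0.740 for endocardial nuclei. With nuclei other than cardiomyocytes as denominator, the fibroblast share differed by -15.0 points, and by -11.6 between IgG and uninjured. The replicate block gave -18.3 for cardiomyocytes, 12.8 for endothelial, -2.87 for endocardial and 9.19 for monocyte and macrophage nuclei (exact permutation, adjusted p = 0.375 each, too few pairs to pass). Leaving out each library gave 7.73 to 10.5 points for monocytes and macrophages. The edgeR test of nuclei numbers between antibody groups gave log2 differences of 1.34 for cardiomyocytes, -0.54 for fibroblasts, 0.61 for endothelial, 0.75 for endocardial, 0.54 for mural and -0.58 for monocyte and macrophage nuclei.

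The r between antibody and injury folds was -0.31 in cardiomyocytes, -0.29 in fibroblasts, -0.28 in endothelial, -0.17 in endocardial, -0.34 in mural and -0.22 in monocyte and macrophage nuclei and -0.39 in all nuclei with the mean of both injured groups, where counts simulated with no antibody effect gave means from -0.078 to 0.024. It was -0.66, -0.60, -0.68, -0.64, -0.76, -0.59 and -0.68 over genes called in IgG against uninjured, a choice that lowers r by itself (means from -0.25 to -0.099 in the same simulated counts), and -0.64 to -0.54 in cardiomyocytes with each library left out. In the simulated counts each gene was drawn on its own, without shifts between libraries that many genes share.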

Other observations

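Of the tests on clock genes, those of time of day and of free RNA were chosen only after the result was seen, as were the 2 lists of clock genes; the test of depth and the splits of the libraries were not.

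Genes of the circadian clock differed between hENPP1mAb and IgG libraries in each of the 6 classes. Dbp (a transcription factor driven by the clock) stood at 43.2 ± 27.0 CPM over all nuclei in hENPP1mAb, 5.76 ± 1.09 in IgG and 40.6 ± 3.94 in uninjured libraries. Arntl, the partner of Clock that peaks in the opposite phase, stood at 29.6 ± 7.89, 130 ± 68.3 and 44.4 ± 2.09 CPM in the same order. Libraries of a group differed: Arntl was 51.9 CPM in IgG 1 but 180 and 156 in IgG 2 and 3. Dbp was 13.7 CPM in hENPP1mAb 1 but 48.8 and 66.9 in hENPP1mAb 2 and 3. Of the genes that cycle with Dbp, 7 of 7 rose in cardiomyocytes and in endothelial nuclei, 4 of 7 in fibroblasts, 4 of 6 in endocardial, 6 of 6 in mural and 5 of 6 in monocyte and macrophage nuclei. Of those that cycle with Arntl, 3 of 4 fell in cardiomyocytes, 2 of 4 in fibroblasts and in endothelial nuclei, 2 of 3 in endocardial, 1 of 3 in mural and 0 of 4 in monocyte and macrophage nuclei (edgeR; 1 of these 4 at an unadjusted p under 0.05, and 0 with DESeq2). The median log2 fold change in the 6 classes ran from 1.485 to 2.37 for the Dbp genes and from -1.25 to -0.54 for the Arntl genes. Between IgG and uninjured libraries the medians of the Dbp genes ran from -2.04 to -1.10, and those of the Arntl genes from 0.31 to 0.87 in 5 classes, with -0.081 in mural nuclei.

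In cardiomyocytes, genes of glycolysis and hypoxia rose in 8 and fell in 1 of 23 between hENPP1mAb and IgG, also when adjusted over the list alone (camera adjusted p = 0.00816; adjusted p = 0.390 with an estimated correlation). Vegfa, the vascular growth factor, rose from 979 ± 304 to 1943 ± 193 CPM. Fkbp5, a gene induced by glucocorticoids, stood at 818 CPM over all nuclei in IgG 1 but at 309 and 289.5 in IgG 2 and 3, at 196 to 407 in hENPP1mAb and at 69.7 to 81.4 in uninjured libraries. Gm42418, a locus that overlaps ribosomal RNA, took 8.15% of UMIs in IgG, 5.77% in hENPP1mAb and 0.234% in uninjured libraries, and Malat1 took 5.54%, 7.39% and 7.87%.

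The Dbp genes had a median above 0 and the Arntl genes below 0 in 6 of 6 classes, which restates the difference for which the lists were chosen and supports no explanation of it. To lift the Dbp genes of cardiomyocytes and fibroblasts from the highest IgG library to each hENPP1mAb library, RNA of the other class richest in them would need a share of counts at least 2.28 times that shown by markers of other classes, which argues against free RNA as the whole cause there. The margin is smaller against the free RNA estimate used elsewhere. In fibroblasts of hENPP1mAb 1 and 3 the shares needed were 93.65% and 58.5%, where that estimate was 68.3% and 33.5%. In the other 4 classes the lowest such ratio was 0.392, in monocytes and macrophages. Free RNA stays open there and in endothelial and endocardial nuclei. In endocardial nuclei the marker share was 117% to 146%, since endothelial markers counted as those of another class, so the ratio cannot decide. In mural nuclei the shares needed were 106.8%, 98.1% and 102.9% in hENPP1mAb 1 to 3 (ratios 1.515 to 1.92). These shares argue against free RNA as the whole cause in mural nuclei. Free RNA also stays open for the Arntl genes, which were not tested for it. With nuclei thinned to at most 1000 UMIs the difference of the medians was 2.53 over all nuclei, against 2.58 without thinning. Random thinning keeps the expected gene proportions of each nucleus, so this value could hardly change, and depth stays open. A time of day of collection that differed between the groups cannot be told apart from an effect of the antibody on the clock, which was not tested, since collection times are not given in the sources used here.

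Other splits of the libraries were run for each count of genes. The 6 injured libraries make 10 splits into 3 and 3, too few for a share under 0.05. For hENPP1mAb against IgG, 1 of 10 splits, the real one, gave as many genes in each class: 3812 in cardiomyocytes (highest other 0), 3874 in fibroblasts (0), 2423 in endothelial (0), 760 in endocardial (1), 1454 in mural (0), and 910 in monocyte and macrophage nuclei (0), and 7292 in all nuclei (0). For lists, the real split called 98 and the highest other 94 (1 of 10), so the number of lists passing camera hardly told the real split from another. The r between antibody and injury folds was -0.56 in cardiomyocytes (-0.43 in the strongest other split), -0.51 in fibroblasts (-0.39), -0.52 in endothelial (-0.44), -0.49 in endocardial (-0.38), -0.61 in mural (-0.47) and -0.61 in all nuclei (-0.51), with 1 of 10 splits as strong in each, and -0.48 in monocyte and macrophage nuclei (-0.49, 2 of 10). For IgG against uninjured, 1 of 35 splits, the real one, gave as many genes in each class. The counts were 6944 in cardiomyocytes (highest other 0), 8259 in fibroblasts (808), 4269 in endothelial (1748), 2270 in endocardial (9), 2812 in mural (646), and 3781 in monocyte and macrophage nuclei (1149), and 11311 in all nuclei (0). This is the smallest share that 35 splits can give, and it was not adjusted over the classes. In both comparisons every other split puts libraries of both groups together, which widens the spread within groups, so fewer genes could pass there. The splits thus do not exclude chance, and they do not tell injury from a batch. Nor can chance be excluded for the number of lists, 92, since 5 of 35 splits called as many and the highest other 98.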
